A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

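Rap1 ChIP-seq was performed with a Rap1 antibody on formaldehyde-crosslinked extracts of strain UKY403, per the labels' protocols, with 2 biological replicates from separate time courses at 0, 2 and 4 h. The isogenic control strain named in the design text was not analysed here. Bowtie, SAMtools and MACS2 and the build sacCer3 are named in the submitters' processing notes, without versions or settings.

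The deposited values are MACS2 peak lists, 1 per time point. Peaks were called with MACS2 2.0.10.20130712, per the file headers, with no control library, a fixed tag extension in place of a fragment model, a q cutoff of 0.05, 1 tag kept per position and strand, and a regional background over 10000 bp. Each header names 1 alignment file per time point; whether it pools both replicates is not given in the sources used here. The summit height is the signal of extended tags at the summit, not scaled for depth, per the file headers. Because 1 tag was kept per position and strand, the height cannot pass 292, the value that all 3 lists reach. The fold enrichment is the ratio of this height to the local background of the same library, as the authors' caller computed it. The -log10 q of each peak was likewise given by the authors' caller, per the file headers. With no control library, regions that fragment or map unevenly are not corrected for. Kept tags made up 40.4, 30.6 and 37.8% of all tags at 0, 2 and 4 h, so sensitivity to weak peaks differed between the lists, and fold enrichments, which fall at capped peaks as background grows, were compared only within a list; 1 check of the height limit across lists is given under the other observations.

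Peaks were assigned to genes with the RefSeq gene table of the R64 assembly, the same assembly as sacCer3, after checking chromosome names and lengths against the last bases of the peak lists. The table holds 6002 protein-coding genes with coding spans that include introns; 96.4% of their lengths are multiples of 3, so they hold no untranslated regions. The strand was read from the systematic name. Coding spans cover 72.8% of the 12071326 bp of the 16 nuclear chromosomes. A summit was coding if inside a coding span, upstream if within 500 bp before a coding start and outside other coding spans, and elsewhere otherwise. Dubious reading frames are not marked in the table and were not removed.

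A peak was retained if it overlapped a 0 h peak by at least 1 bp and new otherwise. Overlaps and coding shares were compared with 10000 random placements of the peaks within their chromosomes. New and retained peaks of a list were compared by the odds ratio of a coding location, with its exact interval. Because retained peaks share their location with 0 h peaks and new peaks avoid them by definition, no p of the planned Fisher's exact test is given. The ratio and the coding share of new peaks were instead set beside 10000 random placements of the new peaks clear of all 0 h peaks, chosen after seeing the data. Fold enrichment and -log10 q were compared with permutation tests of the difference in medians (100000 resamples), all two-sided. The 10 gene lists fixed before the data were examined (ribosomal proteins, glycolysis, translation factors, galactose genes, histone genes, silent mating loci, silencing and telomere factors, proteasome, ribosome biogenesis and environmental stress) were tested with Fisher's exact test against all other protein-coding genes, with Benjamini-Hochberg adjustment over 60 tests. All members were matched in the gene table. These tests run over peaks or genes, which are not replicates. Named genes followed a rule also fixed before the data were examined: by fold enrichment within a list, the highest 10 new coding peaks, 5 new upstream peaks, 5 retained peaks and 5 peaks without a later counterpart per comparison, the highest 10 peaks at 0 h, up to 4 members of each gene list at 4 h, and any member with a peak of lists of up to 10 genes.

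To gauge the effect of depth, height and background of each later peak were divided by its list's number of kept tags relative to 0 h and the Poisson p recomputed against the weakest 0 h peak, and likewise with all tags; both settings were chosen after seeing the data. This matches 1 of these numbers at a time, and the share of kept tags still differs between the lists. Only summit values were scaled, without the caller's length requirement and without random draws for peaks already selected at the higher depth. The shares that pass may therefore be too high, which their intervals do not cover. Alternatives covered q and fold cutoffs, overlap rules, definitions of coding location, equal list lengths, chromosome ends, upstream windows and coding lengths. The planned search for Rap1 motifs and the class of Ty and LTR elements were not run here, because no genome sequence or repeat annotation was used. Functions were tested on simulated data first: in a simulated list with 30% coding summits, 29.6% were recovered, and of 200 gene lists without planted peaks 0 were called. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.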

Results

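Binding of Rap1, the general regulatory factor that activates ribosomal protein genes and coats yeast telomeres, was measured by ChIP-seq in Saccharomyces cerevisiae strain UKY403. In this strain histone H4 is made in galactose and its synthesis stops in dextrose, so that nucleosomes are lost as cells divide. Cells grown in galactose were sampled 0, 2 and 4 h after the move to dextrose, and the question was whether Rap1 occupies sites inside genes when histones run short. The 6 samples fell into 3 groups of 2 biological replicates from separate time courses. The values analysed were 1 peak list per time point, each made from 1 alignment file, so no spread between replicates could be computed and no test compared the time points across samples. The lists rested on 983197, 1483679 and 2327099 tags kept after removal of duplicates at 0, 2 and 4 h, out of 2433135, 4853264 and 6156794 tags. Intervals of shares are 95% exact binomial intervals over peaks and cover counting error only.

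At 0 h Rap1 peaks lay mainly between genes, at chromosome ends and upstream of ribosomal protein and other genes. The 0 h list held 1212 peaks covering 3.89% of the nuclear genome, with a median length of 350 bp. Of these, 667 (55.0%) had their summit within 500 bp upstream of a coding start and outside any other coding span, and 224 (18.5%, interval 16.3 to 20.8%) had it inside a coding span. Peaks placed at random within their chromosomes gave a coding share of 72.7%, and none of 10000 placements came as low (n = 1212 peaks, two-sided p = 0.0002, the smallest they can give). The highest fold enrichments, which throughout are the authors' own values per peak, were at the ends of chromosomes XII (19.9), XIII (19.4), IX (18.8) and VIII (18.1). They were followed by peaks upstream of RPL22B (17.9), HOM6, encoding homoserine dehydrogenase (17.8), ROX3, encoding a Mediator subunit (17.7), and RPL6B (17.6). By their systematic names, ROX3 is the divergent neighbour of the ribosomal protein gene RPL32, which had no summit within 500 bp upstream. The peak was named by the nearer coding start, so it cannot be assigned to ROX3 alone. The right ends of chromosomes III (17.7, with the summit counted as upstream of YCR108C) and XIII (17.6) completed the highest 10. A peak within 1000 bp was listed at 31 of the 32 chromosome ends in each of the 3 lists.

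After 2 h in dextrose, the list contained many peaks inside genes that had none at 0 h. ATP11, which encodes an assembly factor of the mitochondrial ATP synthase, had a new peak with a fold enrichment of 11.7 on chromosome XIV, 43303 to 43690, with its summit 800 bp after the coding start. PDC5, encoding a pyruvate decarboxylase, had a new peak of 9.62, NPL3, encoding an mRNA-binding protein, of 9.13, and HRR25, encoding a casein kinase, of 8.71. The other new coding peaks among the highest 10 lay in YGR210C, YPR084W, LAS1, PHD1, PRP8 and MDM32, with fold enrichments from 8.18 to 9.05. The highest of the 115 new peaks upstream of genes were at YOL160W (5.33), YMR181C (5.15), the lanosterol synthase gene ERG7 (5.09), YLR177W (4.79) and CDC53 (4.72). New coding peaks were far more numerous (1192), so the highest values of these classes were not compared.

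The 2 h list held 2438 peaks, of which 1387 (56.9%, interval 54.9 to 58.9%) shared no base with a 0 h peak and are called new, and 1051 overlapped a 0 h peak and are called retained. Random placement gave 167 retained peaks on average and 218 at most. Of the new peaks, 1192 (85.9%, interval 84.0 to 87.7%) had their summit in a coding span, against 229 (21.8%) of the retained peaks, an odds ratio of 21.9 (17.7 to 27.2). Retained peaks take their location from the 0 h list by definition, so this ratio would be large in any case. With the new peaks placed at random clear of all 0 h peaks it was 11.2 on average and 14.1 at most. These placements gave new peaks a coding share of 75.6%, and none of 10000 came as high as observed (n = 1387 peaks, two-sided p = 0.0002, the smallest they can give). The new coding summits fell in 1047 of 6002 protein-coding genes. The highest retained peaks lay at the ends of chromosomes III (14.6), XV, XIII and X and upstream of REH1 (14.6). REH1 is, by systematic name, the divergent neighbour of the ribosomal protein gene RPS29A, which had no summit within 500 bp upstream. This peak too cannot be assigned to the named gene alone. With 1.51 times the kept tags of the 0 h list, the later list could reach weaker sites. Still, 1308 of the 1387 new peaks (94.3%) passed the 0 h threshold when scaled by the ratio of kept tags, and 1243 (89.6%) when scaled by that of all tags (1.99).

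**Figure D1:**
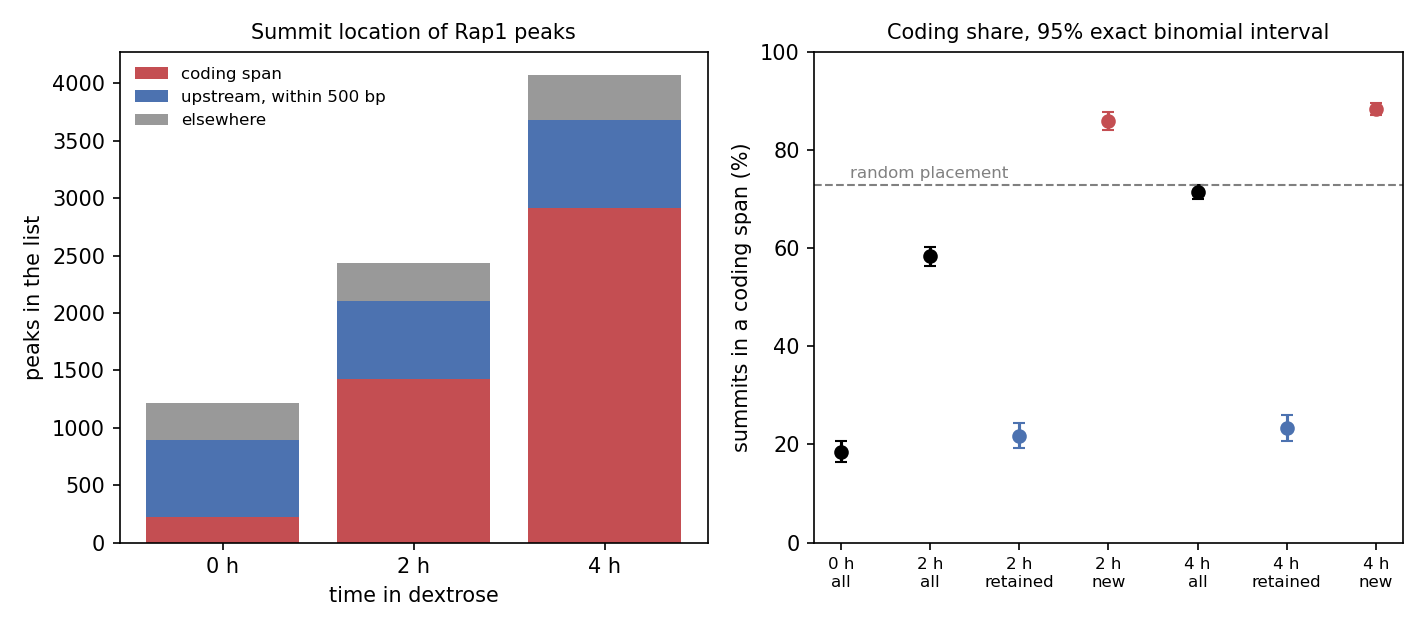
Left, the number of Rap1 peaks (y axis) in the lists of 0, 2 and 4 h (x axis), stacked by summit location. Right, the percentage of summits in a coding span for all, retained and new peaks of each list, with 95% exact binomial intervals and the share from random placement of whole lists as a dashed line; new peaks lie at 85.9% and 88.3%, retained peaks at 21.8% and 23.2%.

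At 4 h PDC5 held the strongest new coding peak, with a fold enrichment of 9.25 on chromosome XII, 411238 to 411778, and its summit 754 bp after the coding start. The next were in BBC1 (9.22), which encodes a protein of actin patches, in the siderophore transporter gene ARN1 (8.91), in LAS1 (8.88), which encodes an endonuclease of rRNA processing, and in RAX2 (8.74). PSF3, encoding a subunit of the GINS replication complex, AIP5, HRR25, YPR084W and YGR210C completed the highest 10, with values from 8.57 to 8.68, and 5 of these 10 genes were also among the highest 10 at 2 h. New upstream peaks were led by the GABA permease gene UGA4 (7.57), PUL3 (6.83), FIT1 (6.43), encoding a cell wall mannoprotein, VPS45 (6.05) and YJR154W (5.32). Each of these 15 regions also overlapped a peak of the 2 h list.

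The 4 h list held 4073 peaks over 10.8% of the nuclear genome, of which 3019 (74.1%, interval 72.7 to 75.5%) were new and 1054 retained, against 281 retained on average under random placement. Of the new peaks 2666 (88.3%, interval 87.1 to 89.4%) had a coding summit, in 2020 genes, against 245 (23.2%) of the retained peaks. The odds ratio was 24.9 (20.7 to 30.0), against 10.4 on average and 12.5 at most with the new peaks placed at random clear of all 0 h peaks. The new peaks' coding share was above that of these placements, 75.8% (n = 3019 peaks, two-sided p = 0.0002, the smallest 10000 placements can give). With 2.37 times the kept tags of the 0 h list, 2524 of the 3019 new peaks (83.6%) passed the 0 h threshold when scaled by the ratio of kept tags, and 2453 (81.3%) when scaled by that of all tags (2.53).

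Over whole lists, the number of coding summits was 224 at 0 h, 1421 at 2 h and 2911 at 4 h, while upstream summits numbered 667, 682 and 766. The coding share was 58.3% at 2 h (interval 56.3 to 60.3%), below random placement (72.7%, n = 2438 peaks, p = 0.0002), and 71.5% at 4 h (70.1 to 72.9%), not distinguishable from random placement (72.8%, n = 4073, p = 0.061). The 4 h share was below random placement among the 1212 peaks with the highest -log10 q, at 55.9% (n = 1212, p = 0.0002), and in 4 other settings. Among the 1212 highest of the 2 h list it was 47.4%. When a summit had to lie at least 200 bp inside both ends of a coding span, the shares were 10.7, 42.2 and 52.5% at 0, 2 and 4 h.

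**Figure D2:**
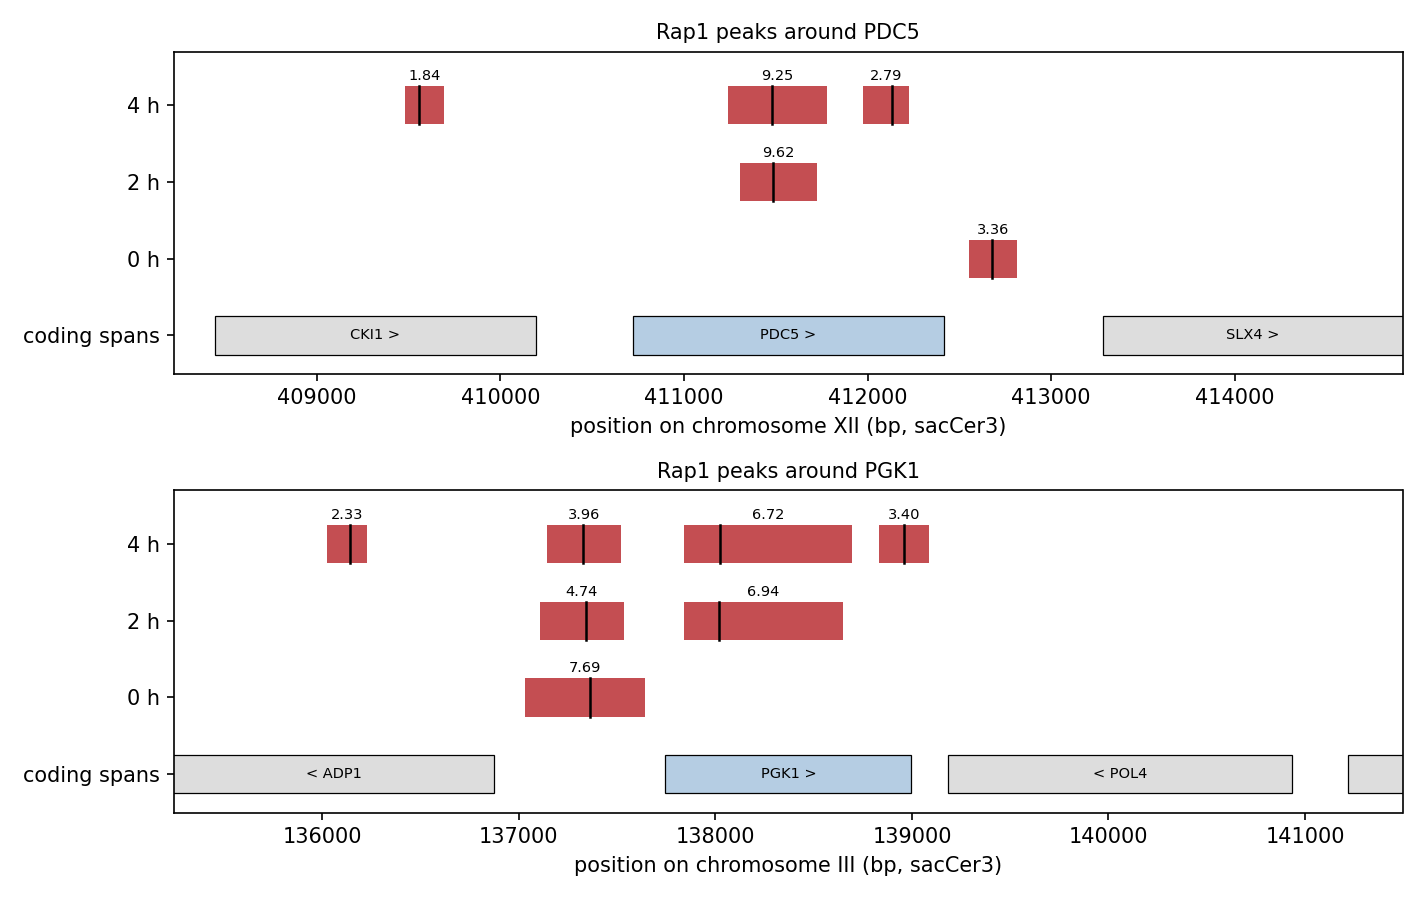
Peaks of the 0, 2 and 4 h lists (red bars, summit as a black line, fold enrichment above) around PDC5 and PGK1, with coding spans below and arrowheads giving their direction; the x axis is the chromosome position in bp. The upstream peak of PGK1 is listed at all 3 times (7.69, 4.74 and 3.96), and peaks inside PDC5 and PGK1 are listed at 2 and 4 h. Fold enrichments of different lists are not comparable.

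Most of the 0 h sites stayed listed. Of the 1212 peaks at 0 h, 1007 (83.1%, interval 80.9 to 85.2%) overlapped a peak in both later lists and 125 in neither. By location, 5 of 224 coding peaks (2.23%), 86 of 667 upstream peaks (12.9%) and 68 of 321 peaks elsewhere (21.2%) overlapped no 4 h peak. The 159 peaks with no 4 h counterpart were weak at 0 h, with a median fold enrichment of 2.63 against 6.44 for the others. The highest of them was an intergenic peak on chromosome VII with its summit at 412562 (6.79), followed by the peak upstream of VPS3 (4.45), an intergenic peak on chromosome X with its summit at 416804 (4.29), the peak upstream of the valyl-tRNA synthetase gene VAS1 (4.11) and an intergenic peak on chromosome VII at 404895 (3.90). Of the 171 with no 2 h counterpart, the same chromosome X peak was the highest, followed by those upstream of GPG1 (4.23), MIN3 (4.14) and the glycerol kinase gene GUT1 (4.09) and an intergenic peak on chromosome XVI (3.90).

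New peaks were weaker than retained peaks of their own list. The median fold enrichment was 2.87 for new and 6.46 for retained peaks at 2 h, and 2.73 and 5.35 at 4 h (permutation test of medians over peaks, two-sided p = 1e-05 for both, the smallest 100000 resamples can give). Median -log10 q was 10.7 and 65.6 at 2 h, and 14.4 and 72.8 at 4 h (permutation test, p = 1e-05 for both). Retained peaks had also passed the threshold of the 0 h list, which had the fewest kept tags. Lower medians of new peaks are therefore favoured by the definition, and no conclusion is drawn from these p-values. The strongest retained peaks at 4 h lay upstream of RPL23A, RPS20 and RPS0B and at the right end of chromosome VIII (10.1 each) and upstream of RPL16A (10.1). New peaks above the retained median fold enrichment numbered 47 of 1387 at 2 h and 265 of 3019 at 4 h. Summit heights reached the same maximum in every list, so the ranking of the strongest peaks within a list is compressed.

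Among the gene lists fixed before the data were examined, ribosomal protein genes had upstream Rap1 peaks at every time. Of 137 members, 108, 110 and 111 had an upstream summit at 0, 2 and 4 h, 108 of them at all 3 times, against 12.4, 12.7 and 14.5% of other genes (Fisher's exact test, Benjamini-Hochberg adjusted over 60 tests, p = 2.2e-66, 4.5e-68 and 4.1e-64). With an upstream window of 250 bp the members numbered 24, 25 and 28 (Fisher's exact test, adjusted p = 3.1e-05, 2e-05 and 2e-05). With a window of 1000 bp they numbered 124, 124 and 125, and with any overlap of the interval 127, 127 and 129. Some members without a summit within 500 bp thus had a peak farther upstream. Fold enrichments upstream of RPS20 were 15.7, 13.6 and 10.1 within the respective lists. Of 15 translation factor genes, 7 had an upstream summit at each time (Fisher's exact test, adjusted p = 0.017, 0.017 and 0.028), among them TEF1, TEF2 and YEF3, which encode elongation factors. The translation factor call was lost at each time with an upstream window of 250 bp (1, 2 and 1 members) and with a window of 1000 bp (Fisher's exact test, adjusted p = 0.068, 0.071 and 0.11). It was also lost at -log10 q of at least 5 at 2 and 4 h (Fisher's exact test, adjusted p = 0.052 and 0.076) and with any overlap of the interval at 4 h (0.082). Upstream summits were at 7, 8 and 6 of 20 glycolysis genes (Fisher's exact test, adjusted p = 0.064, 0.025 and 0.32), including TPI1 (11.2, 7.49 and 6.67) and PGK1. The glycolysis numbers depended on the window, with Fisher's exact test giving adjusted p = 1.5e-06 at 0 h and 0.00035 at 4 h at 1000 bp and no member with a summit at any time at 250 bp. With any overlap of the interval, 17 members at 0 h and 16 at 4 h had an upstream peak (Fisher's exact test, adjusted p = 8.5e-09 and 6.6e-05).

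Inside coding spans, the glycolysis genes stood apart. A coding summit was listed in 2 of 20 members at 0 h, 13 at 2 h and 19 at 4 h, when 36.9% of other genes had one (Fisher's exact test, adjusted p = 0.4, 0.0003 and 1.2e-06). At 4 h the highest were PDC5 (9.25), PFK1 (7.62), encoding a phosphofructokinase subunit, PDC1 (7.27) and TDH3 (6.78), encoding glyceraldehyde-3-phosphate dehydrogenase. Environmental stress genes had a coding summit in 2, 10 and 16 of 25 members (Fisher's exact test, adjusted p = 0.49, 0.11 and 0.031), among them TSL1 (7.46) and TPS1 (6.85) of trehalose synthesis and GLC3 (6.60). The 4 h call was lost at -log10 q of at least 5 (Fisher's exact test, adjusted p = 0.12) and with any overlap of the interval (0.059). Per kb of coding span, their new 4 h summits did not pass either (ratio to other spans 1.71, interval 1.01 to 2.70, exact binomial test, adjusted p = 0.085 over 20 tests). Ribosomal protein genes had coding summits less often than other genes, in 1, 12 and 34 of 137 members (Fisher's exact test, adjusted p = 0.15, 0.0017 and 0.017). These genes are short, however, and per kb of coding span their new summits were not fewer (ratio to other spans 0.945, interval 0.501 to 1.62, at 2 h and 1.14, 0.792 to 1.59, at 4 h). The call was also lost when any overlap of the interval counted (32 and 54 members, adjusted p = 0.53 at 2 h and at 4 h, Fisher's exact test). Ribosome biogenesis genes had them in 0, 2 and 14 of 41 members (Fisher's exact test, adjusted p = 0.64, 0.031 and 0.89, the 2 h value for fewer than other genes), NOG2 being the highest at 4 h (5.18), although the 2 h call was lost at -log10 q of at least 5 (0.076). Translation factor genes had them in 0, 6 and 8 of 15 members (Fisher's exact test, adjusted p = 1, 0.3 and 0.49), led at 4 h by TEF1 (6.41) and SUI1 (5.68). Genes with a closely related copy, such as PDC1 and PDC5 or TEF1 and TEF2, are uncertain as far as tags match both copies, because the handling of such tags is not given in the sources used here.

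**Figure D3:**
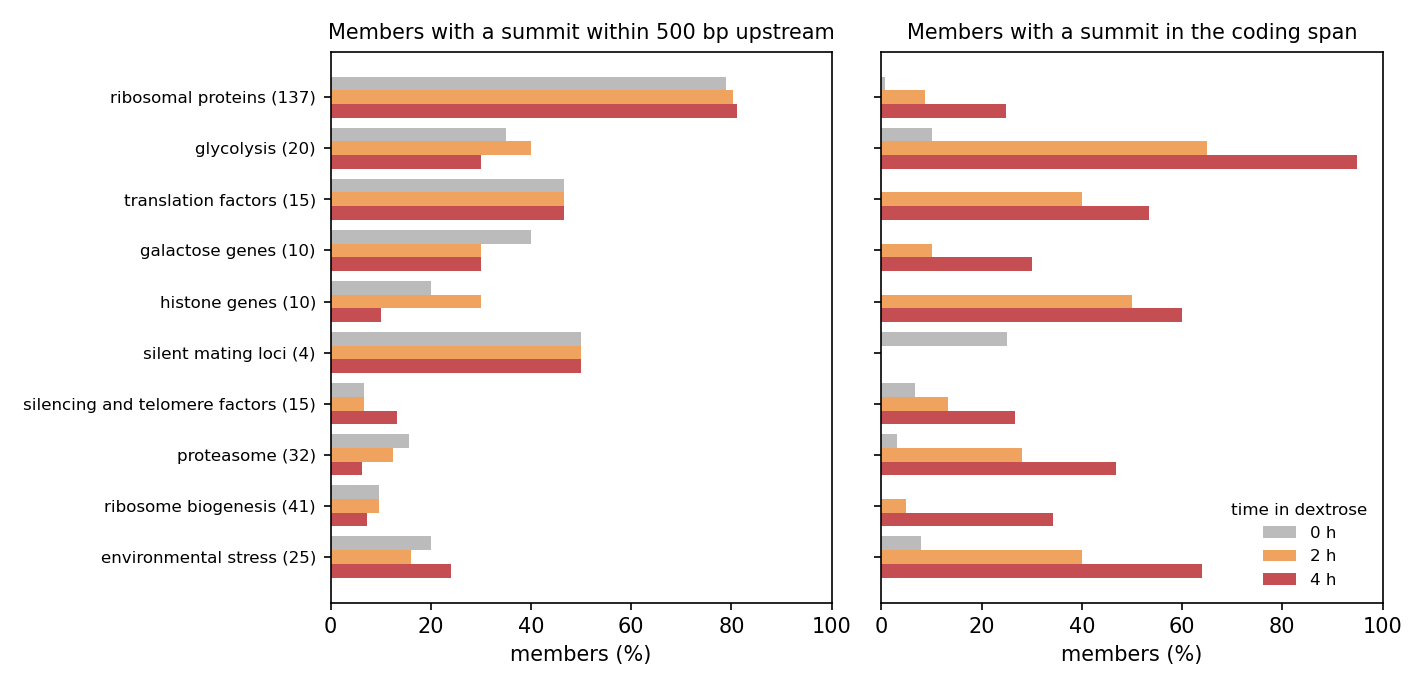
Percentage of members (x axis) of the 10 gene lists (y axis, number of members in brackets) with a Rap1 summit within 500 bp upstream (left) or in the coding span (right) at 0, 2 and 4 h. Upstream bars of ribosomal protein genes stay near 80% at all times, and coding bars of glycolysis genes reach 95% at 4 h.

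The remaining lists passed no Fisher's exact test in either location with the main settings. Calls arose under alternatives: upstream at 0 h for galactose genes with a window of 1000 bp (6 of 10, Fisher's exact test, adjusted p = 0.03), and with any overlap of the interval upstream at 2 and 4 h for histone genes (7 and 8 of 10, 0.014 and 0.013) and in coding spans at 0 h for silent mating loci (3 of 4, 0.018). Per kb of coding span, new summits were denser in histone genes at 2 and 4 h (ratio 8.84 and 3.94, exact binomial test, adjusted p = 0.002 and 0.039). Proteasome genes had coding summits in 1, 9 and 15 of 32 members (Fisher's exact test, adjusted p = 1, 0.6 and 0.49), with RPT5 (8.49) and PUP1 (7.05) the highest at 4 h and an upstream peak at PRE2 (9.93) that is the same peak as that of the divergent ribosomal protein gene RPL11A. Of 10 histone genes, 0, 5 and 6 had a coding summit (Fisher's exact test, adjusted p = 1, 0.14 and 0.4): HHT2 (5.15), HHT1 (4.80), HTB1 (3.90), HHO1 (3.87), HTA1 (2.52) and HTA2 (2.07) at 4 h. No summit was listed in or upstream of the H4 genes HHF1 and HHF2. Whether these genes are intact in UKY403, where H4 synthesis depends on galactose, was not examined here. Their lack of summits therefore cannot be read as a lack of Rap1 binding. Of the galactose genes, GAL1 and GAL10 shared an upstream peak at all times (7.35, 7.17 and 4.46), and the summit upstream of the galactose sensor gene GAL3 at 0 h (6.73) belonged to a wide peak that was listed at all times, with its summit in TRP1 at 2 h (5.57) and 4 h (4.76). Whether UKY403 carries plasmid copies of these galactose-gene and TRP1 regions is not given in the sources used here, so their values cannot be read as binding at the chromosomal sites alone. New coding peaks of this list at 4 h lay in PGM2 (6.06), GCY1 (3.32) and GAL4 (2.58). HMLALPHA1 and HMLALPHA2, at a silent mating locus, shared an upstream peak at all times (7.92, 8.57 and 6.83). At 0 h a peak was also listed upstream of MATALPHA2 (10.5), with its summit 109 bp before the coding start, against 112 bp at HMLALPHA2. The handling of tags that match both loci is not given in the sources used here, so this signal cannot be assigned to the silent locus alone. A coding summit in HMRA1 was listed at 0 h (2.44) and an overlapping 4 h peak had its summit past the coding end. Of 15 silencing and telomere genes, 1, 2 and 4 had a coding summit, with CDC13 (7.93) and SIR4 (4.18) the highest at 4 h, and RAP1 itself had an upstream peak at each time (16.8, 12.9 and 8.64). Values of different lists are given side by side for location only and were not compared.

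Along coding spans, new summits at 4 h were less frequent near the 3' end. When each span was divided into 3 equal parts, 35.4, 35.2 and 29.3% of the 2666 new coding summits fell in the first, middle and last part, and the last part was below random positions in the same genes (33.3%, n = 2666, adjusted p = 0.0012 over 6 tests, 10000 draws). The first and middle parts did not pass (n = 2666, adjusted p = 0.07 and 0.088). With positions kept clear of 0 h peaks, a setting chosen after seeing the data, the last part at 4 h stayed lower (33.5% expected, n = 2666, adjusted p = 0.0012) and the first part passed as higher (32.3% expected, n = 2666, adjusted p = 0.0036). At 2 h the shares were 34.5, 34.3 and 31.2%, none passing (n = 1192, adjusted p = 0.49, 0.49 and 0.18), although within coding spans of at least 1000 bp the last part was also lower at 2 h (29.5%, unadjusted p = 0.01). Genes with the most new summits at 4 h, named after their values were seen, were YBL005W-B and YMR045C (6 each) and DNF2, PRB1, PYC2, YFL002W-A and YGR161W-B (5 each). Of these, YBL005W-B, YMR045C, YFL002W-A and YGR161W-B are retrotransposon reading frames, whose near-identical copies make the assignment of tags uncertain.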

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

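Of 96 alternative values of the main results, 86 kept their direction and side of the threshold, or stayed within 1.5 times the reported count. Among these are the comparisons of new with retained peaks in coding location, fold enrichment and -log10 q, whose direction the definition favours. Merging overlapping entries changed no peak number and is counted as well. The tally therefore overstates how far the results withstood other settings. Settings chosen after seeing the data were the scaling to the kept tags or all tags of 0 h, leaving out repeat-like coding spans (a suffixed systematic name and at least 1200 bp), placements clear of 0 h peaks and the overlap rules for the fold enrichment and -log10 q tests. The odds ratio of coding location for new against retained peaks ranged from 19.5 to 30.2 at 2 h and from 25.6 to 28.7 at 4 h, and was 1.96 and 2.40 times that of new peaks placed clear of 0 h peaks. Peak numbers moved at a fold enrichment of at least 3, to 1486 at 2 h and 2128 at 4 h, and new peaks at a -log10 q of at least 10 in the later list, to 731 and 1915, since weaker peaks are removed. The 4 h coding share passed the test, below random placement, at a -log10 q of at least 5 (71.0%, n = 3785 peaks, p = 0.018) or 10 (68.3%), among the 1212 highest peaks (55.9%), scaled to the 0 h kept tags (70.5%, p = 0.0044) and without repeat-like spans (70.3%, p = 0.001). Without repeat-like spans the share is lowered by construction, since their peaks were dropped while the placements still counted these spans as coding. No conclusion is drawn from that setting. The last part of coding spans passed at 2 h in spans of at least 1000 bp (29.5%). Of 240 alternative values of single gene lists, 217 stayed the same, 13 lost and 7 gained a call on the same side of an odds ratio of 1, and 3 changed side. These were, at 250 bp, upstream summits at 0 of 20 glycolysis genes at 2 h and at 1 of 15 translation factor genes at 4 h, and with any overlap, upstream peaks at 8 of 10 histone genes at 4 h (Fisher's exact test, adjusted p = 0.013). The glycolysis and translation factor cases lost a call and the histone case gained a call, so none passed in both directions. The cause of these changes was not tested. No paired analysis was possible because the lists carry no replicate numbers, and leaving out a replicate could not be run for the same reason. The motif search and its alternatives were not run. Depth limits the 0 h list most, with the fewest kept tags.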

Other observations

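The comparisons of summits per kb, of summit distances, of tRNA genes, of wide peaks, of placements clear of 0 h peaks, of scaled depth and of peaks under the height limit below were chosen after seeing the data. Most new coding peaks of 2 h lay at the same place at 4 h. Of 1192 such peaks, 1178 (98.8%) overlapped a 4 h peak, against 18.4% on average and 23.2% at most under random placement. Their summits lay a median of 13 bp from the 4 h summit, with 65.3% within 20 bp, against 60 bp and 17.7% for a summit drawn at random in the 2 h peak. Merging the 3 lists gave 4249 regions: 995 present at all times, 1287 at 2 and 4 h, 1726 at 4 h alone and 47 at 2 h alone.

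Corrected for coding length, new 4 h summits were denser in glycolysis genes (0.832 per kb against 0.299 in other spans, ratio 2.78, interval 1.78 to 4.15, exact binomial test, adjusted p = 0.00026 over 20 tests) and in the short histone genes (ratio 3.94, 1.28 to 9.22, adjusted p = 0.039), the latter from 5 summits. At 2 h the ratios were 3.38 (1.79 to 5.80) and 8.84 (2.87 to 20.7), again from 5 summits in the histone genes (exact binomial test, adjusted p = 0.002 for both). Ribosomal protein genes did not differ detectably at 4 h (ratio 1.14, 0.792 to 1.59). Ribosome biogenesis genes had fewer at 2 h (ratio 0.264, 0.0543 to 0.772, exact binomial test, adjusted p = 0.034). tRNA genes overlapped a peak in 28 of 275 cases at 0 h, against 12.9 on average for randomly placed tRNA genes, and in 17 at 4 h, against 36.9, and new 4 h peaks overlapped 2, against 24.4. Only 5 tRNA genes overlap a coding span, which random placement did not preserve, so lower numbers are expected for lists rich in coding peaks. A higher number is likewise expected at 0 h, when most peaks lay outside coding spans. Neither an excess nor a lack of peaks at tRNA genes can be read from these numbers. Peaks within 20000 bp of chromosome ends made up 8.66% of the 0 h list, above random placement (5.27%, n = 1212, adjusted p = 0.001). Of new peaks they made up 3.97% at 2 h and 4.57% at 4 h, against 5.15 and 5.00% for placements clear of 0 h peaks (n = 1387 and n = 3019, unadjusted p = 0.046 and 0.3). The widest peaks of each list included the rDNA on chromosome XII (3578 bp at 4 h, fold enrichment 1.31), the CUP1 repeat on VIII (2183 bp), chromosome III from 113300 to 115229 (1930 bp, 5.14) and TRP1 on IV (1560 bp, 4.76). Whether UKY403 carries plasmid copies of the last pair of regions is not given in the sources used here, so their values, and that of the same peak near GAL3 at 0 h, cannot be read as binding at the chromosomal sites alone. Of the 2666 new coding summits at 4 h, 121 fell in repeat-like spans, among them YBL005W-B and YMR045C.

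The 4 h list was longer than the 0 h list. Sequencing depth as the whole cause is argued against, since 83.6% (interval 82.2 to 84.9%) of the new 4 h peaks would pass the 0 h threshold when scaled by the ratio of kept tags, and 81.3% (79.8 to 82.6%) by that of all tags, where under 5% was the prediction. These passing shares rest on scaled summit values alone and may be too high. Chance calls at the q threshold as the whole cause are argued against too, since 42.8% of the new 4 h peaks overlapped a 2 h peak, and random placement reached 13.9% at most. The 1726 merged regions listed at 4 h alone gain no support from this overlap. Neither test excludes a background shared by the later libraries, such as uneven fragmentation, because no control library entered the calls. The loss of histone H4 and the change from galactose to dextrose occurred together in all later samples, and which of them matters stays open because the control strain was not analysed here.

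The limit that duplicate removal sets on summit heights bears on any comparison of fold enrichments between lists, which was made here for this check alone. It is a candidate explanation for lower fold enrichments of the strongest retained peaks at 4 h: among 187 with a height of at least 250 at 0 h, the median ratio of 4 h to 0 h heights was 1.01, while their background ratio was 1.77. Of the 580 retained peaks expected to stay under the limit at the kept tags of 4 h, the 312 of height 50 or more at 0 h had a height ratio over background ratio of 0.754 (95% bootstrap interval 0.715 to 0.792, 2000 resamples), and the 268 of lower height had 1.08 (0.977 to 1.14). Peaks listed at 0 h but not at 4 h, which were weak at 0 h, are left out of this set. Their absence can raise the value for lower heights, so it cannot show whether such peaks dropped. The value over all 580 was 0.866 (0.831 to 0.901). Whether duplicate removal accounts for the lower ratio at heights of 50 or more stays open. Heights over those predicted with 1 tag per position were 0.894 (0.846 to 0.937) for peaks of height 50 or more and 1.17 (1.08 to 1.26) for the others. These values cannot decide it, since only retained peaks were used and the split was by the 0 h height, which itself enters the ratio. A lower occupancy by Rap1 was not tested.

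Whether new coding peaks at 4 h in part reflect tag signal over strongly transcribed genes was also asked. Ribosomal protein, glycolysis and translation factor genes were taken as such genes without RNA levels of their members. Together they held 1.50 times as many new summits per kb as other coding spans (interval 1.16 to 1.91), the direction this explanation predicts. This excess rests on the glycolysis genes: without them the ratio was 1.19 (0.866 to 1.61), and for ribosomal protein genes alone 1.14 (0.792 to 1.59), a split chosen after seeing the data. The excess is thus not shown for the 3 lists in common and does not by itself point to transcription. The 3 lists held 68 of the 2666 new coding summits, and other spans held 0.298 per kb. RNA levels and a control library were not used here, so transcription and binding of Rap1 inside these genes stay open.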
